A study of Zea mays with 14 samples.

How the data were processed

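Chromatin and RNA were profiled in maize (Zea mays) seedlings of the inbred line B73 at 14 days, harvested as shoots and roots. The labels list 14 libraries of 7 assays in 2 organs, with 1 library per assay and organ. The assays were chromatin immunoprecipitation followed by sequencing for H3K4me3, H3K9ac, H3K27me3 and H3K36me3, sequencing of DNA digested with McrBC, mRNA sequencing and small RNA sequencing. McrBC cuts DNA that carries methylcytosine, and short fragments were gel purified after digestion, per the labels' protocols, so that sequenced fragments come from methylated DNA. Tissue was pooled from several seedlings and the chromatin of parallel immunoprecipitations was combined before library construction, per the labels' protocols. The 2 small RNA libraries were not analysed here. Groups were taken from the sample titles.

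The authors deposited 3 kinds of file. The first is a list of peaks for each of the 10 chromatin libraries, which holds only a clone, a start and an end, without a score, so peaks could not be ranked by strength. Whether peaks were called on single or combined libraries is not given in the sources used here; each list belongs to 1 library. The second is a gene table for each organ with 186790 gene models, labelled as not being transposable elements (TE). For each mark it gives the marked length and a depth, and for mRNA a covered length, a depth and a mean depth per covered base. The deposited depth values are signal (summed base coverage), not read counts. All mRNA depths were exact multiples of the read length of 35 bases. Summed over gene models, they correspond to 21615685 reads in shoot and 21406798 reads in root. The lowest mean depth above 0 was 2.55 in shoot and 2.53 in root, so genes below about that depth are listed at 0, and a gene listed at 0 is not shown to be silent. The authors' mark depths were multiples of 1 step per library within a tolerance of 0.05, from 0.316 for DNA methylation in root to 2.14 for H3K27me3 in root, with a step of 1 for H3K4me3 in shoot. They therefore carry a single scaling factor per library, whose basis is not given in the sources used here. The depth of a mark counts only coverage within its peaks. The total number of reads of the chromatin libraries is unknown here. The mRNA coverage was not scaled. The third file is a table of 161415 gene models typed as EVI, PRO, UPRO or TE, the last being transposable elements. Its deposited read column holds coverage of both organs summed: every sum of shoot and root depth of the 36465 genes above 0 in both organs occurs in it. Its column headed as reads per kb equals coverage divided by covered length. The aligner, peak caller, genome build and annotation are not given in the sources used here.

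Gene identifiers of the organ tables differ only in zero padding and were joined by number. None of them matched an identifier of the gene name table used here, so genes are not named, the gene lists fixed before the data were examined were not run, and the rule for named genes reduced to at most 2 identifiers higher in each organ. The organ tables hold no coordinates. Genes were given a typed model, and with it a length, only where the summed coverage and the covered length allowed a single pair, which was the case for 3572 genes. In simulated data with known pairs, 100% of the 3819 pairs made this way were correct. The simulation held a single model per gene and no overlapping or TE models, so it does not give the accuracy of the real pairs. Peaks are placed on 15498 clones and models on contigs within clones, and these coordinates were not joined below the level of the clone. Gene models are redundant: 21627 genes, equal to 30.3% of those with a mark, repeated all mark depths and lengths of an earlier gene. The first gene of each such set is not in this number. Of the typed models, 17.9% overlapped another on the same strand by at least 50% of their span. The marked length exceeded the span of the model in up to 20.4% of paired genes, so regions counted for a gene extend beyond it.

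Peak overlap was counted from 1 bp. The value without an association came from 100 random placements of the peaks within their own clone, whose extent was taken as the largest peak end on it. This placement ignores that genes cluster within clones. In simulated peaks of which 30.0% were planted on a target, 32.7% overlapped, against 4.22% by random placement. Genes were split by mRNA into those listed at 0 and 5 equal classes of mean depth above 0. Spearman's rho across genes was computed between mark depth and mean mRNA depth, and between the log2 ratios of shoot over root. Genes are not independent replicates, so rho has no p-value. Ratios used a pseudocount at the 5th percentile of values above 0, equal to 12 reads for mRNA, and understate differences of low genes. A gene was called higher in an organ at 4-fold or more on this scale, with at least 146 reads in the higher organ, the median of values above 0. It was called similar below 2-fold. In simulated libraries of the 52223 genes above 0 in either organ, 100% of genes changed 8-fold and 0% of genes changed 2-fold passed the 4-fold limit. The simulation held counting noise only, changed only well covered genes and set no depth limit below which genes are listed at 0. It therefore checks the computation and does not give an error rate for the real calls. The TE share of clones was computed over 13902 clones with at least 5 models and an extent of at least 50 kb. With 1 library per assay and organ there are no replicates: differences between libraries have no replicate check and were not tested for significance, and 95% intervals of shares (Wilson) and of their differences cover counting error only. They take each peak or gene model as independent, so the redundancy of gene models makes the intervals of gene shares too narrow.

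Alternatives were chosen before the data were examined, except those named as added in the part on processing. They covered the overlap needed, merging of peaks within 1 kb, the pseudocount, the level filter, the fold limit, the scaling of libraries, and gene length. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.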

Results

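Maize seedlings of the inbred line B73 were separated into shoots and roots at 14 days, and 4 histone modifications, DNA methylation and mRNA were compared between the organs and with each other. H3K4me3 and H3K9ac are marks usually found at the start of active genes, H3K36me3 is usually found along transcribed genes, and H3K27me3 is the mark of Polycomb repression. DNA methylation was read from fragments released by McrBC, an enzyme that cuts methylated DNA. Each assay had 1 library per organ, so there were no replicates. Summed over gene models, mRNA coverage equalled 21615685 reads in shoot and 21406798 in root, where a read in overlapping models can count more than once. Mean mRNA depth was above 0 for 44501 of the 186790 gene models in shoot and for 44187 in root, with 36465 above 0 in both. These gene models are labelled as not being transposable elements (TE), so the shares of gene models given below do not describe TE models.

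Shoot libraries had more and longer peaks than root libraries for H3K4me3, H3K9ac, H3K27me3 and DNA methylation, whereas H3K36me3 had more peaks in root. H3K4me3 had 48926 peaks in shoot and 39410 in root, covering 45.4 and 26.5 Mb. H3K9ac showed a wider gap, with 47604 peaks over 60.8 Mb in shoot and 26028 peaks over 16.3 Mb in root. H3K27me3 was the scarcest mark by number, with 14592 peaks in shoot and 6875 in root, covering 9.01 and 3.13 Mb. H3K36me3 had 20935 peaks in shoot and 27069 in root, but the root peaks were shorter (median 915 bp against 1204 bp), so that the covered lengths were 31.7 and 29.3 Mb. DNA methylation peaks were the most numerous in shoot and the shortest, with 57514 in shoot and 37914 in root and medians of 188 and 162 bp. H3K4me3 marked 25.7% of gene models in shoot (95% Wilson interval 25.5 to 25.9%) and 19.8% in root (19.6 to 20.0%). The corresponding shares were 24.8% and 12.1% for H3K9ac, 3.55% and 1.26% for H3K27me3, 11.47% and 14.0% for H3K36me3, and 4.19% and 3.68% for DNA methylation. The depth of H3K9ac summed over genes, after the authors' scaling, was 4.95 times as high in shoot as in root, with 4.26 times the marked length summed over genes. Its median depth per marked base was 1.44 in shoot and 1.31 in root. For H3K27me3 the ratios of summed depth and marked length were larger, at 5.24 and 5.81. They were 2.48 and 1.46 for H3K4me3, 0.977 and 1.08 for H3K36me3, and 1.37 and 0.962 for DNA methylation. Peak number also follows sequencing depth and the efficiency of each immunoprecipitation, which the deposited lists do not separate from the organ.

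Root peaks of H3K4me3 and H3K9ac nearly always overlapped shoot peaks, root peaks of H3K27me3 and H3K36me3 did so less often, and DNA methylation peaks of both organs were mostly found in a single organ. Of the root peaks, 89.96% overlapped a shoot peak for H3K4me3 (95% Wilson interval 89.7 to 90.3%) and 91.3% for H3K9ac (90.9 to 91.6%). The share was 65.0% for H3K27me3 (63.8 to 66.1%) and 53.9% for H3K36me3 (53.3 to 54.5%). For DNA methylation it was 10.3% (9.99 to 10.6%). Random placement gave 4.98%, 5.83%, 2.05%, 4.11% and 0.978% in the same order. In the other direction, 69.5% of H3K4me3, 47.3% of H3K9ac, 29.3% of H3K27me3, 67.5% of H3K36me3 and 6.67% of DNA methylation peaks of shoot overlapped a root peak. The share for a mark thus depended on which organ had the larger set.

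**Figure D1:**
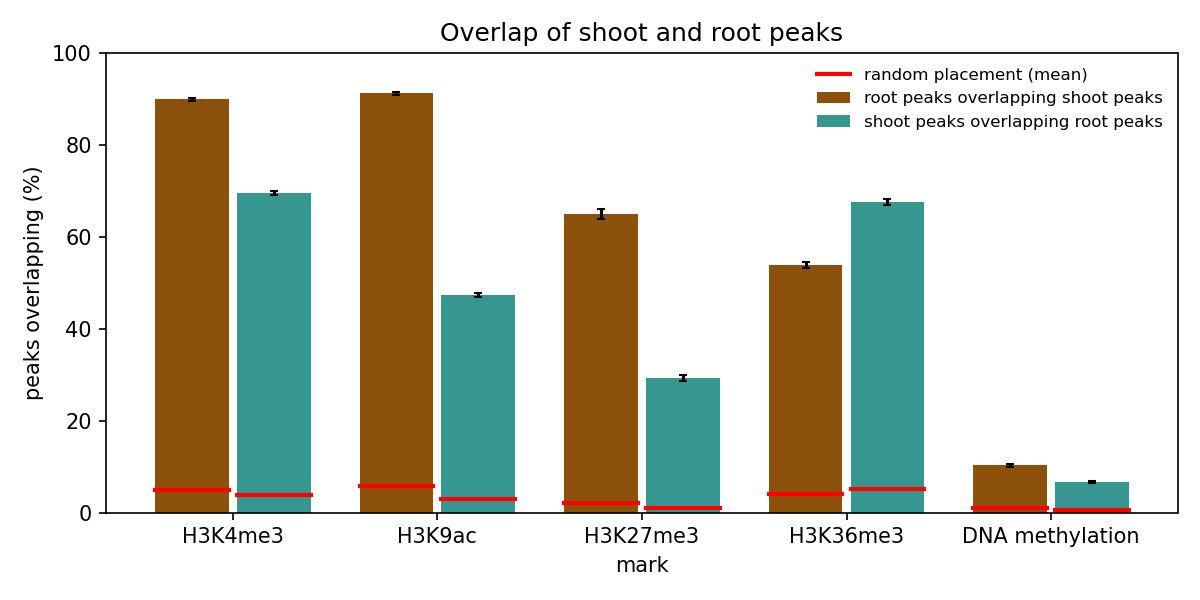
Percentage of peaks of each mark that overlapped a peak of the other organ by at least 1 bp (y axis), for root peaks (brown) and shoot peaks (green). Error bars are 95% Wilson intervals, and red lines are the mean of 100 random placements; H3K4me3 and H3K9ac peaks of root reached 89.96% and 91.3%, and DNA methylation peaks 10.3%.

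Within each organ, H3K4me3, H3K9ac and H3K36me3 lay together, a part of H3K27me3 lay on H3K4me3, and DNA methylation avoided H3K4me3 and H3K9ac. H3K4me3 peaks overlapped H3K9ac in 81.5% of cases in shoot (95% Wilson interval 81.2 to 81.9%) and 51.3% in root (50.9 to 51.8%), which is 12.7 and 23.0 times the random value. H3K9ac peaks overlapped H3K4me3 in 80.9% of cases in shoot and 77.5% in root. H3K36me3 peaks overlapped H3K4me3 in 72.9% of cases in shoot (72.3 to 73.5%) and 62.0% in root (61.4 to 62.6%). H3K27me3 peaks overlapped H3K4me3 in 33.8% of cases in shoot (33.1 to 34.6%) and 27.03% in root (26.0 to 28.1%), against 4.06% and 2.46% by random placement. Their overlap with H3K36me3 was 4.75% in shoot and 5.57% in root, against 1.99% and 1.82% by random placement. DNA methylation peaks overlapped H3K4me3 in 1.13% of cases in shoot and 0.939% in root, 0.499 and 0.630 times the random value. They overlapped H3K36me3 at the random level in shoot (1.53% against 1.51%) and at 2.74 times that level in root (4.43% against 1.62%). The relation to H3K36me3 depended on peak length. With the peaks at or above the median length of each list, an alternative chosen after the data were seen, the overlap of H3K27me3 with H3K36me3 was below random in both organs (0.971% against 1.56% in shoot, 0.668% against 1.37% in root). DNA methylation was then at 0.843% against 1.13% in shoot and at 4.41% against 1.24% in root. With H3K4me3, longer peaks of DNA methylation overlapped in 0.319% and 0.361% of cases (0.203 and 0.332 times random) and those of H3K27me3 in 23.8% and 17.3% (7.47 and 8.86 times). When at least 50% of the H3K36me3 peak had to be covered, its overlap with H3K4me3 was 54.6% in shoot. Peaks of different marks come from separate libraries of pooled tissue, so overlap does not show that the marks lie on the same chromosome copies.

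**Figure D2:**
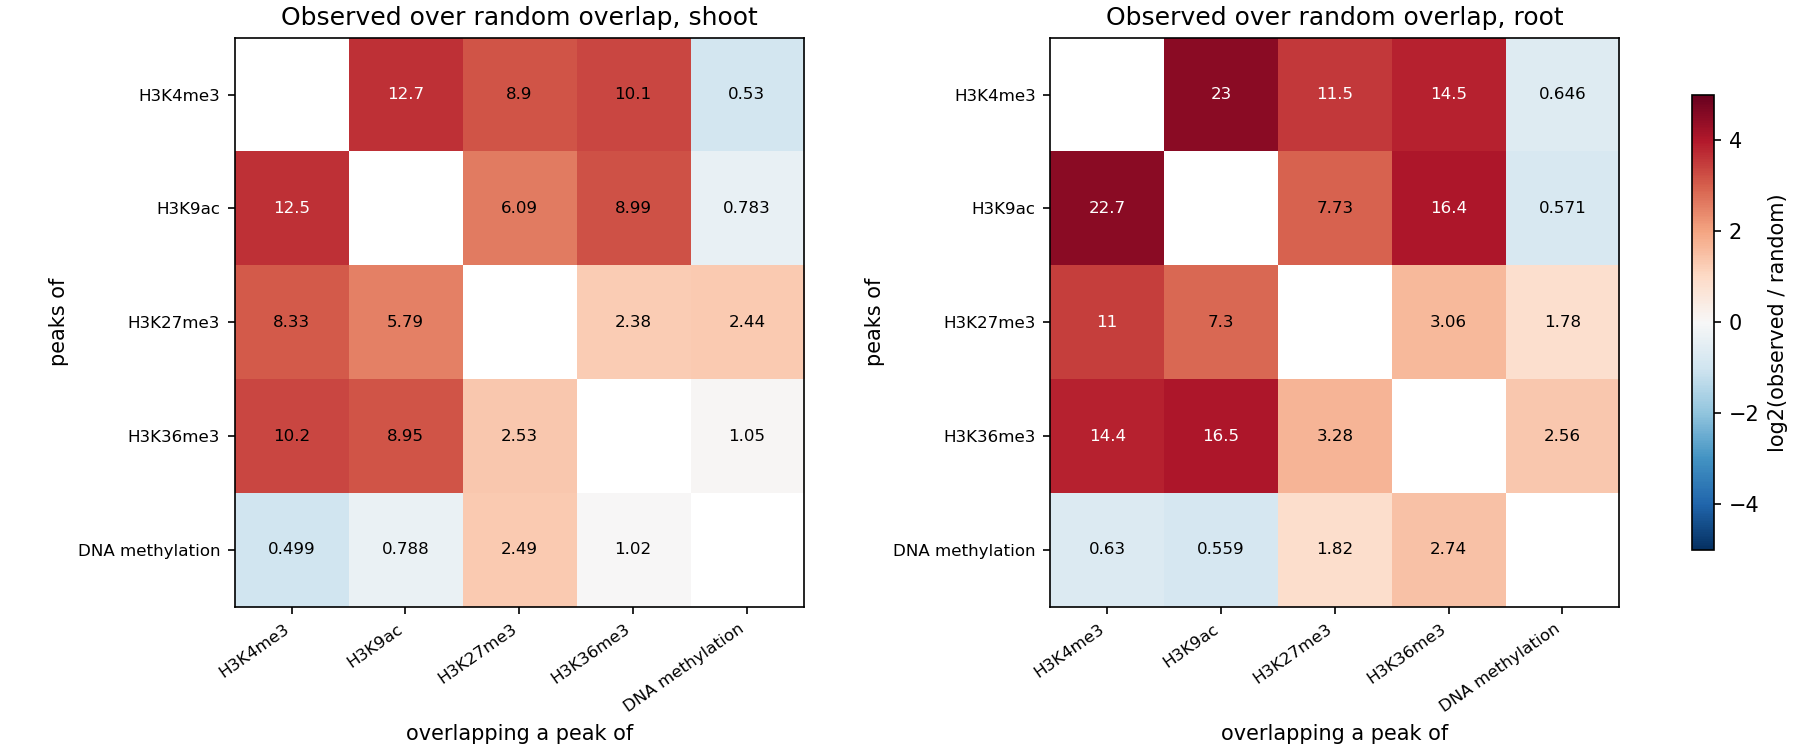
Overlap of the peaks of 1 mark (rows) with those of another (columns), divided by the mean of 100 random placements, for shoot (left) and root (right); colour gives the log2 of the printed ratio. H3K4me3 and H3K9ac had the highest ratios (12.7 in shoot and 23.0 in root), and DNA methylation with H3K4me3 was below 1 in both organs.

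The 3 marks H3K4me3, H3K9ac and H3K36me3 were several times more frequent on genes with mRNA than on genes listed at 0, DNA methylation was less frequent, and H3K27me3 had no steady course across the classes. In shoot, H3K4me3 was on 14.9% of the 142289 genes listed at 0 (95% Wilson interval 14.7 to 15.0%), on 52.3% of genes in the lowest class above 0 (51.3 to 53.4%) and on 68.7% in the highest class (67.7 to 69.7%). In root it was on 10.3%, 41.4% and 61.2% of these classes. H3K9ac went the same way across classes, from 14.0% to 66.5% in shoot and from 4.73% to 47.0% in root. H3K36me3 went from 4.06% (3.96 to 4.17%) to 47.3% (46.3 to 48.4%) in shoot and from 5.91% to 45.4% in root. H3K27me3 was on 3.46% of genes listed at 0 (3.37 to 3.56%) and on 3.82% of all genes above 0 (3.64 to 3.998%) in shoot, and on 1.13% (1.07 to 1.18%) and 1.70% (1.59 to 1.83%) in root. Over the 5 classes above 0, from low to high, it was on 4.47%, 3.99%, 3.37%, 2.99% (2.65 to 3.36%) and 4.26% in shoot and on 1.74%, 1.81%, 1.65%, 1.44% and 1.87% in root. DNA methylation went from 4.58% of genes listed at 0 (4.47 to 4.69%) to 2.33% in the highest class (2.03 to 2.66%) in shoot and from 3.97% to 2.22% in root. Across genes of shoot, Spearman's rho between mark depth and mean mRNA depth was 0.476 for H3K4me3, 0.472 for H3K9ac, 0.437 for H3K36me3, 0.00704 for H3K27me3 and -0.0354 for DNA methylation. The values in root were 0.454, 0.426, 0.428, 0.0214 and -0.0285. Much of this relation was the step between genes listed at 0 and the rest: among genes above 0, rho in shoot was 0.174 for H3K4me3, 0.111 for H3K9ac and 0.188 for H3K36me3. In the 3572 highly covered genes that could be given a length, rho in shoot was 0.00396 for H3K4me3, -0.161 for H3K9ac and 0.0184 for H3K36me3, and in root 0.0848, 0.0788 and -0.137. Within classes of length the values were 0.0932, -0.0738 and 0.116 in shoot and 0.161, 0.159 and 0.0256 in root.

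**Figure D3:**
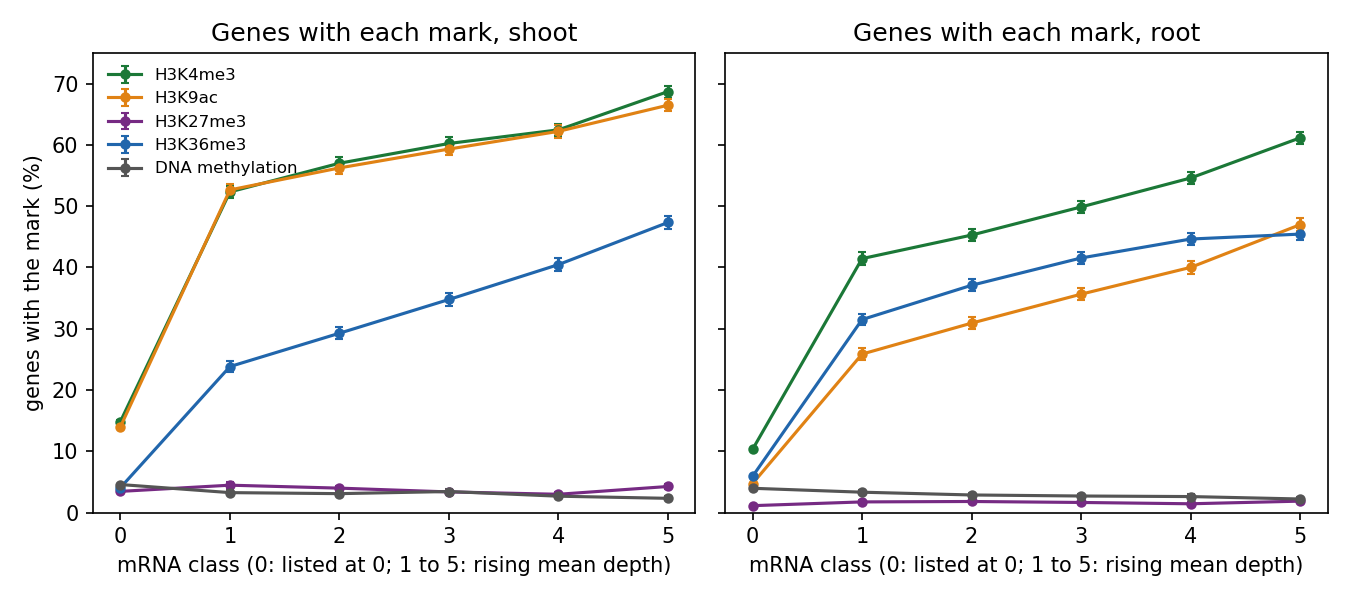
Percentage of genes with each mark (y axis) by class of mRNA in the same organ (x axis), for shoot (left) and root (right); error bars are 95% Wilson intervals. H3K4me3 in shoot goes from 14.9% of genes listed at 0 to 68.7% of the class of highest mean depth, while H3K27me3 and DNA methylation stay below 5%.

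Combinations of marks separated genes further. Of the 16626 genes with H3K4me3, H3K9ac and H3K36me3 in shoot, 75.5% had mRNA above 0 (95% Wilson interval 74.9 to 76.2%), compared with 49.9% of the 20388 genes with H3K4me3 and H3K9ac alone (49.3 to 50.6%). Where H3K27me3 joined H3K4me3 and H3K9ac, as in 2781 genes of shoot, 29.4% were above 0 (27.8 to 31.2%), but in the 230 genes where it joined all 3 marks the share was 77.4% (71.6 to 82.3%). Genes with H3K27me3 alone were above 0 in 14.7% of 1594 cases (13.1 to 16.6%), and genes with DNA methylation alone in 8.21% of 6349 cases (7.56 to 8.91%). In root, 76.6% of the 13632 genes with H3K4me3, H3K9ac and H3K36me3 were above 0 (75.9 to 77.3%), as were 38.8% of the 10400 genes with H3K4me3 alone and 9.23% of the 5642 genes with DNA methylation alone. Root genes with H3K4me3 and H3K9ac were above 0 in 62.1% of 5183 cases (60.7 to 63.4%) and, with H3K27me3 as well, in 57.2% of 269 cases (51.3 to 63.0%), so that these intervals overlapped.

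Genes with more mRNA in root carried H3K27me3 in shoot far more often than genes with similar mRNA, and of the 5 marks H3K4me3 had the highest correlation with mRNA in its organ difference. At the 4-fold limit, 3526 genes had more mRNA in shoot, 2414 had more in root and 16865 were under 2-fold apart. The counts depended on the settings: higher in shoot and in root numbered 1784 and 875 with a pseudocount 10 times larger, 2288 and 1269 by mean depth, and 6505 and 5529 without the level filter. H3K27me3 in shoot was on 19.2% of the genes higher in root (95% Wilson interval 17.7 to 20.8%), on 8.82% of those higher in shoot (7.93 to 9.80%) and on 1.99% of those with similar mRNA (1.79 to 2.21%). In root, H3K27me3 was on 6.21% of the genes higher in root (5.32 to 7.25%), 4.59% of those higher in shoot (3.95 to 5.34%) and 0.771% of those with similar mRNA (0.650 to 0.914%). Both groups of organ-biased genes thus carried this mark more often than similar genes, in both organs. Of the genes above the level filter, those with H3K27me3 in root only were higher in shoot in 40.1% of 177 cases (33.2 to 47.5%) and higher in root in 14.1% (9.75 to 20.0%). Those with the mark in shoot only were higher in shoot in 22.3% of 988 cases (19.8 to 25.0%) and higher in root in 34.2% (31.3 to 37.2%). Genes marked in both organs had shares of 26.1% and 35.9% of 348, and genes with the mark in neither organ had 12.4% and 7.62% of 25269.

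H3K36me3 was less frequent on genes that differed between organs. It was on 49.6% of genes with similar mRNA in shoot (95% Wilson interval 48.8 to 50.3%), on 38.1% of those higher in shoot (36.5 to 39.7%) and on 11.1% of those higher in root (9.87 to 12.4%). In root the shares were 57.5%, 26.9% and 25.8%. H3K4me3 in shoot was on 70.8% to 74.2% of all 3 groups, whereas in root it was on 47.6% of genes higher in shoot (46.0 to 49.3%), on 61.4% of similar genes (60.7 to 62.1%) and on 67.6% of genes higher in root (65.7 to 69.4%). H3K9ac in root was on 22.04% of genes higher in shoot (20.7 to 23.4%), 47.3% of genes with similar mRNA (46.6 to 48.1%) and 44.4% of genes higher in root (42.4 to 46.4%). Across genes, rho between the log2 ratios of shoot over root of mark and mRNA was 0.391 for H3K4me3 over 31542 genes, 0.199 for H3K9ac over 30691, -0.190 for H3K27me3 over 2952, 0.181 for H3K36me3 over 23297 and 0.0296 for DNA methylation over 2547. With mark and mRNA at or above the median in both organs, rho was 0.0311 for H3K36me3 and -0.381 for H3K27me3. This setting keeps fewer genes, at most 348 for H3K27me3. With a pseudocount 10 times larger, rho was 0.119 for H3K9ac.

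The genes of highest log2 ratio were listed at 0 in the other organ. Zm031678 and Zm100286 had 35119 and 28148 reads in shoot and were listed at 0 in root. They had equal mark values, with H3K27me3 over 670 bp in shoot and 177 bp in root and H3K4me3 over 932 bp in shoot, so they do not count as independent cases. Zm005093 and Zm128736 had 32163 and 28542 reads in root and were listed at 0 in shoot. Zm005093 carried H3K27me3 over 475 bp in shoot and had none listed in root, and Zm128736 had none listed in either organ. Both root genes had more H3K4me3 in shoot than in root (1037 against 409 bp, and 563 bp against none listed) and H3K9ac over 634 bp in shoot with none listed in root. Their H3K9ac values were equal, so for this mark they do not count as independent cases either. More of these marks in shoot was the rule whatever the mRNA: the median log2 ratio of shoot over root in marked genes higher in root was 0.43 for H3K4me3 and 1.39 for H3K9ac, and 1.08 and 1.60 in those with similar mRNA. Gene names and positions were not used here, since no identifier matched the name table. Of the genes higher in shoot, 2188 were listed at 0 in root, and 1237 of those higher in root were listed at 0 in shoot. Because such genes can lie just below the depth limit, each was also set at the lowest listed mean depth over the length covered in the other organ. The counts at 4-fold were then 2401 and 1543. This level, called the upper bound below, assumes a covered length no longer than in the other organ.

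**Figure D4:**
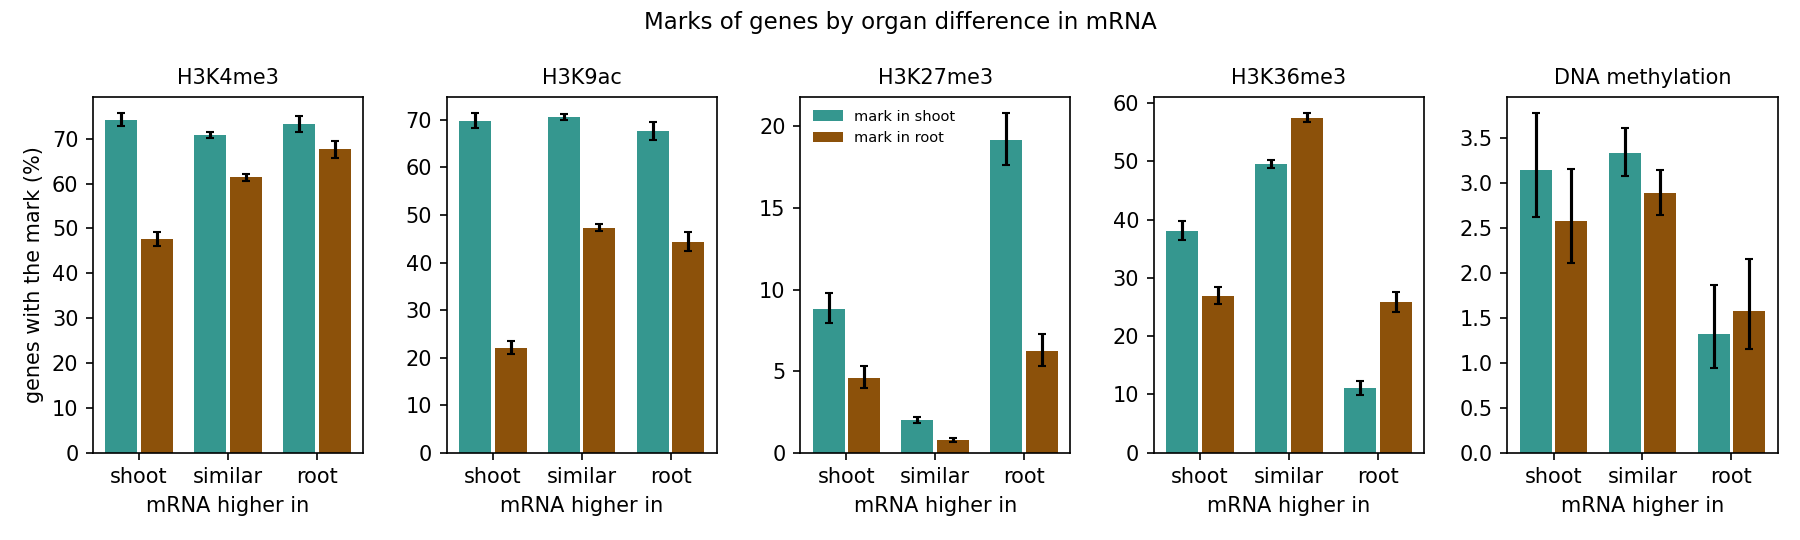
Percentage of genes with each mark in shoot (green) and in root (brown) among genes with at least 4-fold more mRNA in shoot, genes under 2-fold apart and genes with at least 4-fold more in root; the y axes differ between panels and error bars are 95% Wilson intervals. H3K27me3 in shoot is on 19.2% of genes higher in root and 1.99% of similar genes.

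Models typed as transposable elements were numerous but held little mRNA, and clones rich in them had fewer peaks of the 4 histone marks. TE models were 35.7% of the 161415 typed models and held 3.06% of the mRNA coverage of both organs together. PRO models were 33.3% of the models with 55.8% of the coverage, and EVI models were 15.7% with 36.9%. Of the EVI models, 1099 were also labelled with a transposon biotype, and their coverage is not in the TE share. A single read was the whole coverage of 50.7% of TE models, and the 10 TE models of highest coverage held 24.6% of all TE coverage. Across 13902 clones, rho between peak density and the TE share of models was -0.481 in shoot and -0.444 in root for H3K4me3, -0.463 and -0.369 for H3K9ac, -0.324 and -0.367 for H3K36me3, and -0.158 and -0.103 for H3K27me3. For DNA methylation it was 0.0483 in shoot and 0.0413 in root. The methylation peaks covered 0.527% of the clone extent in shoot and 0.294% in root. These values of rho therefore describe the listed peaks and not all methylated DNA. With the clones in 4 equal groups by TE share, H3K4me3 peaks in shoot went from 3.18 per 100 kb in the group of lowest share to 1.30 in that of highest share, and DNA methylation peaks from 2.40 to 2.55 per 100 kb. The TE share is a share of all models of a clone, so a high share also means a low share of other models. Peak density was not adjusted for the number of other models. How reads matching several positions were placed was not examined. The meaning of EVI, PRO and UPRO is not given in the sources used here, and the typed table lists only models with at least 1 read.

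**Figure D5:**
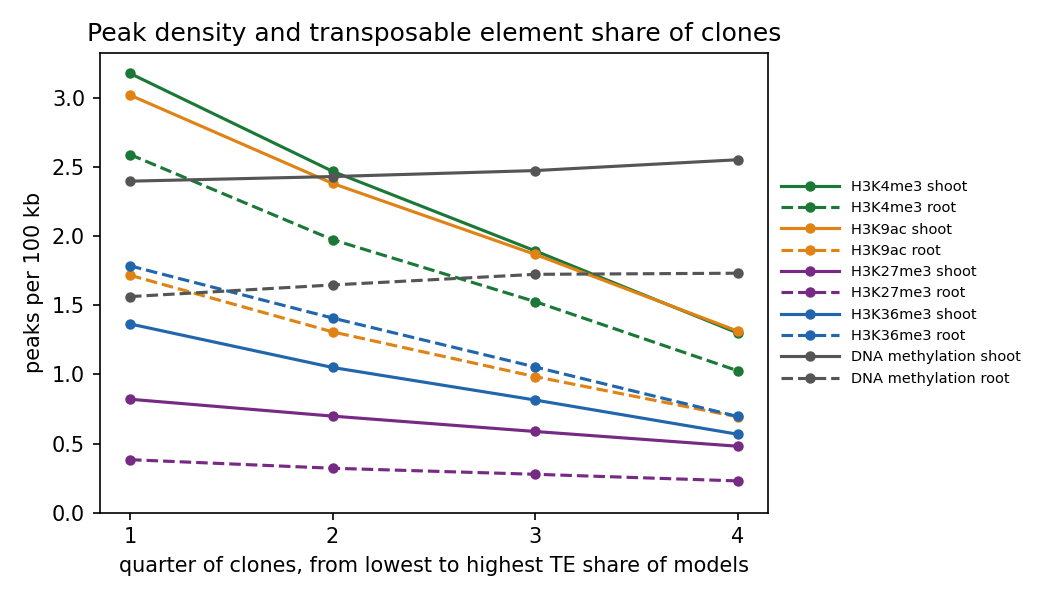
Number of peaks per 100 kb (y axis) in 4 equal groups of the 13902 clones ordered by the share of TE models (x axis), for each mark in shoot (solid lines) and root (dashed lines). H3K4me3 in shoot goes from 3.18 to 1.30 peaks per 100 kb, and DNA methylation in shoot from 2.40 to 2.55.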

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

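H3K36me3 stood apart from the other 4 marks in the direction of its organ difference. It had 1.29 times as many peaks in root as in shoot (27069 against 20935), whereas H3K4me3, H3K9ac, H3K27me3 and DNA methylation had 0.806, 0.547, 0.471 and 0.659 times as many. Its covered length was lower in root, at 0.924 times that of shoot, and its summed scaled depth over genes was 0.977 times as high in shoot as in root. The difference between marks was not tested, since each rests on 1 library per organ.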

How the results depend on the processing

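The alternatives named as added were chosen after seeing the data; all others were fixed before. Of 165 values under alternatives, 71 stayed within the counting interval of the reported value or within 1.5 times a reported count, 84 moved beyond it and 10 turned sign, in 6 results. Peak numbers and ratios of covered length all stayed within 1.5 times when peaks within 1 kb were merged. Where no cause is named, the cause was not tested. No paired analysis was possible because each assay had 1 library per organ, and no library could be left out. Alternatives that rank peaks by a score were not run, since the lists hold none, and those for gene lists were not run, since no gene was named. The depth of the chromatin libraries is unknown, and genes under a mean depth of about 2.55 are listed at 0, which limits what can be said of low genes.

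With at least 50% of a peak to be covered, root peaks in shoot peaks came to 88.3% (H3K4me3), 60.7% (H3K27me3), 51.9% (H3K36me3) and 7.61% (DNA methylation). Overlap with H3K4me3 in shoot and root was 69.2% and 71.6% for H3K9ac, 54.6% and 52.9% for H3K36me3, 28.9% and 22.6% for H3K27me3, and 0.935% and 0.725% for DNA methylation, and DNA methylation in H3K36me3 in shoot was 1.43%. A stricter overlap lowers these shares by construction. With the peaks at or above the median length of each list (added), root peaks in shoot peaks were 80.0% (H3K4me3), 74.8% (H3K9ac), 46.3% (H3K36me3) and 8.45% (DNA methylation). Overlap with H3K4me3 was then 71.5% and 69.6% for H3K9ac, 71.7% and 54.7% for H3K36me3, 23.8% and 17.3% for H3K27me3, and 0.319% and 0.361% for DNA methylation, and DNA methylation in H3K36me3 in shoot was 0.843%. Against random placement of these longer peaks, H3K27me3 in H3K36me3 went from 2.38 to 0.624 times in shoot and from 3.06 to 0.487 times in root, and DNA methylation in H3K36me3 in shoot from 1.02 to 0.746 times.

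For mark and mRNA, rho among genes above 0 was 0.174 (H3K4me3), 0.111 (H3K9ac), -0.00931 (H3K27me3), 0.188 (H3K36me3) and -0.0175 (DNA methylation) in shoot, and 0.179, 0.178, -0.00232, 0.106 and -0.0211 in root. Within classes of gene length, over the 3572 genes with a length, the values were 0.0932, -0.0738, -0.00308, 0.116 and 0.0147 in shoot and 0.161, 0.159, -0.0198, 0.0256 and 0.0421 in root. Among those longer than 1 kb they were 0.0774 (H3K4me3), -0.133 (H3K9ac), 0.0889 (H3K36me3) and -0.106 (DNA methylation) in shoot, and 0.138, 0.106, -0.0146 (H3K27me3), -0.0936 (H3K36me3) and -0.0660 (DNA methylation) in root. The set of genes moved these values before length did: with no length class, the same 3572 genes, all above 0 in both organs and with a median of 1437 reads in shoot against 151 for genes above 0, gave 0.00396 for H3K4me3 and -0.161 for H3K9ac in shoot and -0.137 for H3K36me3 in root. Pearson's r was 0.454 and 0.448 for H3K4me3 and H3K9ac in shoot and 0.444 and 0.409 for H3K4me3 and H3K36me3 in root. With 1 gene per set of identical marks (added), rho was 0.465, 0.464, 0.0226, 0.428 and -0.0123 in shoot, and 0.445 (H3K4me3), 0.420 (H3K9ac), 0.0274 (H3K27me3) and -0.00622 (DNA methylation) in root.

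For the organ differences, rho of H3K4me3 was 0.325 with a pseudocount 10 times larger, 0.379 with 1 gene per set (added), 0.374 with mean depth (added) and 0.381 with genes listed at 0 set at their upper bound (added). H3K9ac was at 0.119 with the larger pseudocount and 0.170 with both values at or above the median, where H3K27me3 was at -0.381, H3K36me3 at 0.0311 and DNA methylation at 0.0839. The median setting keeps fewer genes, at most 348 for H3K27me3. H3K36me3 was at 0.152 with the larger pseudocount, 0.165 with mean depth and 0.162 at the upper bound. Genes higher in shoot and in root numbered 1784 and 875 with the larger pseudocount, 6505 and 5529 without the level filter and 2288 and 1269 by mean depth. Those higher in root numbered 4781 at 2-fold and 1543 at the upper bound. Scaling to the same total or by a trimmed mean moved all log2 ratios by -0.01 and 0.08 and both counts by less than 1.5 times. H3K27me3 in shoot was on 7.54% and 12.8% of genes at least 2-fold higher in shoot and in root (added) and on 9.88% and 23.9% at 8-fold (added). It was on 2.41% of similar genes at the upper bound. For H3K36me3 in root, rho with the TE share was -0.395 over models longer than 1 kb.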

Other observations

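Of the tests given here, those on the bottom 10% of H3K27me3 genes, on the median shift of H3K9ac and its depth per marked base in genes with similar mRNA, and on DNA methylation against mRNA were chosen only after the result was seen.

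Genes with both DNA methylation and H3K36me3 were more often listed with mRNA above 0 than genes with DNA methylation alone. In root, 45.7% of the 416 genes with these 2 marks and no other had mRNA above 0 (95% Wilson interval 40.9 to 50.5%), compared with 9.23% of the 5642 genes with DNA methylation alone (8.51 to 10.0%) and 48.4% of the 4766 genes with H3K36me3 alone (47.0 to 49.8%). In shoot the shares were 41.9% of 160 genes (34.5 to 49.6%), 8.21% of 6349 genes and 57.8% of 2540 genes. Peaks of DNA methylation overlapped H3K36me3 at 2.74 times the random level in root and 1.02 times in shoot (3.57 and 0.746 times with the longer peaks of each list), and this difference was not tested. The length marked by H3K36me3 also differed along the mRNA classes: its median per marked gene was 954.5 bp in genes listed at 0 and 1449 bp in the highest class in shoot, and 884 and 934.5 bp in root.

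Many genes with mRNA carried none of the 5 marks. These were 13268 of the 44501 genes above 0 in shoot and 16982 of the 44187 in root. Their median mean depth was 5.33 in shoot and 5.29 in root, below the 7.78 and 7.55 of genes with H3K4me3, H3K9ac and H3K36me3 together.

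Most genes with H3K27me3 in shoot had no H3K27me3 listed in root. Of the 663 genes in the top 10% by shoot depth, 38.8% were marked in root (95% Wilson interval 35.1 to 42.5%). Recovery of at least 80% was predicted if a lower depth of the root library were the cause. In the same top 10%, the share was 91.9% for H3K4me3, 77.6% for H3K9ac and 84.4% for H3K36me3. The reads of the chromatin libraries and the basis of their scaling are unknown here. The limit of 80% is therefore not calibrated, and a lower depth of the root library stays open. This holds also for the genes of lowest depth, where 7.40% were marked in root, since a shallow library and a true absence predict the same. For genes above the level filter, the values argue against greater activity in root as the cause of most of the absence there. Of such genes in the top 33.3% by shoot depth, 45.1% of 253 marked in shoot only and 46.1% of 165 marked in both were higher in root. The difference was -1.001 percentage points (95% interval -10.8 to 8.77). Over all shoot-marked genes above the filter it was -1.71 (-7.55 to 4.14). The filter kept 988 genes marked in shoot only and 348 marked in both. The rest of the 6622 genes marked in shoot were not examined, so for them this cause stays open. The amount of the mark went against mRNA in part: the rho of organ differences was -0.190 over 2952 genes. It was -0.381 with both values at or above the median, in at most 348 genes. The median log2 ratio of shoot over root was, however, 2.22 in marked genes higher in root, 1.18 in similar ones and 1.46 in those higher in shoot. A part played by activity therefore stays open, as do a weaker immunoprecipitation in root and an organ difference unrelated to mRNA, both untested.

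H3K9ac had less summed scaled depth in root, as did H3K4me3, H3K27me3 and DNA methylation. Shoot over root was 4.95, 2.48, 5.24 and 1.37 in this order, and 0.977 for H3K36me3. Of the 7794 genes with similar mRNA marked by H3K9ac in both organs, 99.53% had a larger sum in shoot, but 99.38% also had a longer marked length there (median 1298 against 626 bp), so the sum does not show more acetylation per region. Per marked base, 88.3% of these genes had more in shoot (95% Wilson interval 87.6 to 89.0%, median log2 ratio 0.55), between the limits set for and against a shift of nearly all genes, and the shift was larger for H3K4me3 (99.1% of 10167 genes, 0.95) and not seen for H3K36me3 (44.0% of 6813 genes, -0.06). Genes with more mRNA in shoot did not carry the summed excess of H3K9ac alone, as its median log2 ratio was 1.60 in genes with similar mRNA. In the top 10% of root depth the median was 1.27, above the 0.5 set as the limit against library size, but the basis of the authors' scaling is not given in the sources used here, so library size cannot be told apart from the organ, and the efficiency of immunoprecipitation and an organ difference in acetylation stay open, untested.

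DNA methylation peaks of the organs mostly lay apart. If each library caught a part of a larger methylated space, long peaks were predicted to recur. Of the longest 10% of root peaks, 19.1% overlapped a shoot peak (95% Wilson interval 17.9 to 20.4%), against 6.59% of the shortest 10%. Random placement of the longest gave 1.41%. The interval reaches the limit of 20% set against this explanation, but that limit is not calibrated. The peaks covered only 0.527% of the clone extent in shoot and 0.294% in root. Partial sampling this sparse need not make long peaks recur, so it cannot be told apart from an organ difference. A shoot peak lay within 1 kb of 17.7% of root peaks, against 5.67% by random placement. Among genes methylated in root, 50.7% of the top 10% by depth were also marked in shoot (95% Wilson interval 47.0 to 54.4%). In the bottom 10% the share was 15.0%. From shoot to root the shares were 23.9% and 18.7%. The organ differences in methylation and mRNA had a rho of 0.0296. Partial sampling of methylated DNA would lower such a value, so it does not decide on a relation with mRNA. It also leaves an organ difference in methylation open.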
